A study of Homo sapiens with 4 samples.

How the data were processed

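Total RNA from 293T cells was profiled on Affymetrix human U133A arrays, with 2 arrays of untreated cells and 2 of cells exposed to camptothecin. The deposited values are signal intensity per probe set, and MAS 5.1 was used for the array analysis per the labels. The values are on a linear scale with 1 decimal, from 0.1 to 19093.2. The mean after trimming 2% at each end lay between 200.06 and 200.07 on the 4 arrays, so each array had been scaled to a common brightness before deposition. The arrays' medians were 63.1 and 59.4 for untreated replicates 1 and 2, and 62.3 and 62.1 for camptothecin replicates 1 and 2. The 100 brightest probe sets held 14.6% to 17.5% of the summed signal. Detection calls were not used here, so no statement is made on whether a transcript is present. The number of arrays limits the precision.

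Of 22283 probe sets, 68 are controls of the manufacturer and were not tested for the comparison, which left 22215. Over all probe sets 19071 have 1 gene symbol and 1043 have several, 6 controls among them, and 2107 that are not controls list no gene. Symbols were looked up by Entrez identifier for 19059 of them, and 12 kept the symbol of the platform annotation, giving 11963 distinct genes. Probe sets were tested when their mean signal over the 4 arrays was at or above the median of the 22215, which left 11111. Each gene was represented by its probe set with the highest mean signal among those with 1 gene symbol. A probe set whose name ends in _x_at, which can bind several transcripts, was taken only where the gene had no other.

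Signals were transformed as log2(signal + 16) without further scaling. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes moderation with an intensity trend, two-sided), and p-values were adjusted by Benjamini and Hochberg over the 11111 probe sets, with a threshold of 0.05. The model had 2 residual degrees of freedom per probe set and a prior of 13.2. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333, so none is given for single genes. Genes that differed at least 2-fold in the same direction in all 4 treated-untreated pairs were counted without a test. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

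The groups, the test, the alternatives, 25 gene lists and the rule for naming genes were fixed before the data were examined. The 24 lists with at least 5 tested genes were compared with the other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. The blood cell markers, with 2 tested genes, had no set test. With an estimated correlation, camera also refers its statistic to the 2 residual degrees of freedom, so that even a strong shift can fail to pass. None of the 24 lists passed that way, against 17 with the preset value, 10 of them higher and 7 lower. By fry, which tests whether a list's own genes move one way on balance, 15 lists passed. Counts adjusted over the list alone used the p-values of a list's members only. Lists share members: the p53 list shares 4 with the apoptosis list, and ATF3, ACTA2 and SFN are each in the p53 list and in others. The lists of neuronal, blood cell, fibroblast and epithelial genes stand for other cell types, although 293T cells express some neuronal and epithelial genes.

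The rule named the 14 genes with the largest rise and the 14 with the largest fall among those past the threshold whose camptothecin values both lay beyond both untreated values. It also named up to 4 members of each list with the smallest p, and a few genes whatever their values, which included TOP1, CDKN1A, MDM2, MYC, GAPDH and ACTB. A further gene of that last group is not reported here. Other genes were named after their values were seen: the remaining members of any list direction with 5 or fewer genes, ATF4 and DDIT3, and the genes of the mitochondrial ribosome and HLA families.

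The alternatives were quantile normalization, scaling to a common median, scaling to the 18 hybridisation spike-in probe sets, a pseudocount of 1 or 64, no filter on signal, the brightest 30% of probe sets, no probe sets with names in _x_at or _s_at, no intensity trend, the mean over a gene's probe sets, a block for the sample number, the estimated correlation, fry, and leaving out each array in turn. The spread of a group left with 1 array was taken to be that of the other group. The procedure was tested on simulated data with 2 arrays per group in 20 draws of 200 changed probe sets each: 77.2% of 2-fold and 14.1% of 1.5-fold changes were recovered, and 5.48% of the calls were wrong. A shifted list was called in 10 of 10 draws and the same list without a shift in 0. The noise was drawn independently for each probe set, so this does not test list calls among correlated genes. Variances came from the fitted prior, and the 200 changed probe sets were far fewer than the 4015 called in the data.

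Gene lengths are the genomic spans of RefSeq genes in the human assembly GRCh38.p14 and were known for 6802 of the 6803 genes tested. For each list, 10000 random lists matched on length class and signal quintile were drawn from the genes tested. A list's median is called inside its matched lists where it lies within their central 95%.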

Results

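The series measured mRNA levels in 293T cells, a human embryonic kidney line that carries the large T antigen of simian virus 40. Total RNA from 2 samples of untreated cells and 2 samples of cells kept in 2 µM camptothecin for 48 h was hybridised to U133A oligonucleotide arrays, 1 array per sample. Camptothecin is a plant alkaloid that traps DNA topoisomerase I on DNA. The design has 1 comparison, treated against untreated cells, which asks which transcripts differ after exposure to the drug. Signals are given below in the arbitrary units of the arrays as mean ± SD with n = 2, and fold changes on the log2(signal + 16) scale, which understates the change of dim transcripts. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples.

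The 4 arrays had nearly equal overall brightness, with trimmed mean signals from 200.06 to 200.07. Over the 11111 probe sets tested, Pearson's r was 0.980 between the untreated arrays and 0.982 between the camptothecin arrays, against 0.894 to 0.913 between arrays of different groups. These correlations are across probe sets, which are not independent replicates. The median absolute log2 difference was 0.19 and 0.16 within the groups and 0.36 to 0.40 between them. The number of arrays, 2 per group, limits the precision of every value.

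Transcripts of known p53 target genes were higher in camptothecin, and those of the integrated stress response, which includes genes of amino acid supply, were lower. Neither list was past the test with an estimated correlation (adjusted p = 0.276 and 0.281). TP53I3, an oxidoreductase gene that p53 activates, rose from 72.7 ± 6.93 to 1388 ± 59.4, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 178 ± 14.8 to 1442 ± 63.99. In the other direction, SLC7A11, the cystine-glutamate exchanger, fell from 537 ± 16.5 to 32.5 ± 4.45, and the proto-oncogene MYC, a transcription factor that drives growth, fell from 959 ± 24.9 to 149 ± 10.5. ASNS, asparagine synthetase, fell from 3668 ± 71.9 to 630 ± 48.3.

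Of the 6803 genes tested with 1 representative probe set each, 1465 were higher and 1118 were lower in camptothecin by limma's moderated test at an adjusted p under 0.05. Among them, 363 were higher and 328 lower by 2-fold or more. Counted by probe set, 2209 were higher and 1806 lower, so that 55.0% of the calls were higher. Scaling to a common median turned the majority, with 1891 probe sets higher and 2147 lower (46.8% higher). Scaling the arrays to the hybridisation spike-ins moved that share to 66.1% and the median log2 fold change of the probe sets tested from 0.036 to 0.14, so changes below are relative to the arrays' common brightness. The mean log2 spike-in signal was 8.94 and 9.32 in untreated replicates 1 and 2, and 9.03 and 9.02 in camptothecin replicates 1 and 2. The direction of the spike-in shift thus rests on untreated replicate 2. By the usual rule for 2 arrays per group, 404 genes differed at least 2-fold in the same direction in all 4 treated-untreated pairs, 212 of them higher and 192 lower. The same 2-fold limit was passed by 27 genes between the untreated arrays and by 30 between the camptothecin arrays. Another tested probe set existed for 809 of the called genes, and for 12 of these it was called in the opposite direction. Leaving out any of the arrays lowered the number of calls, and no called gene was then called in the opposite direction. A fit with 1 array in a group has less power. A call lost in this way, here and below, therefore need not rest on the array left out.

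**Figure D1:**
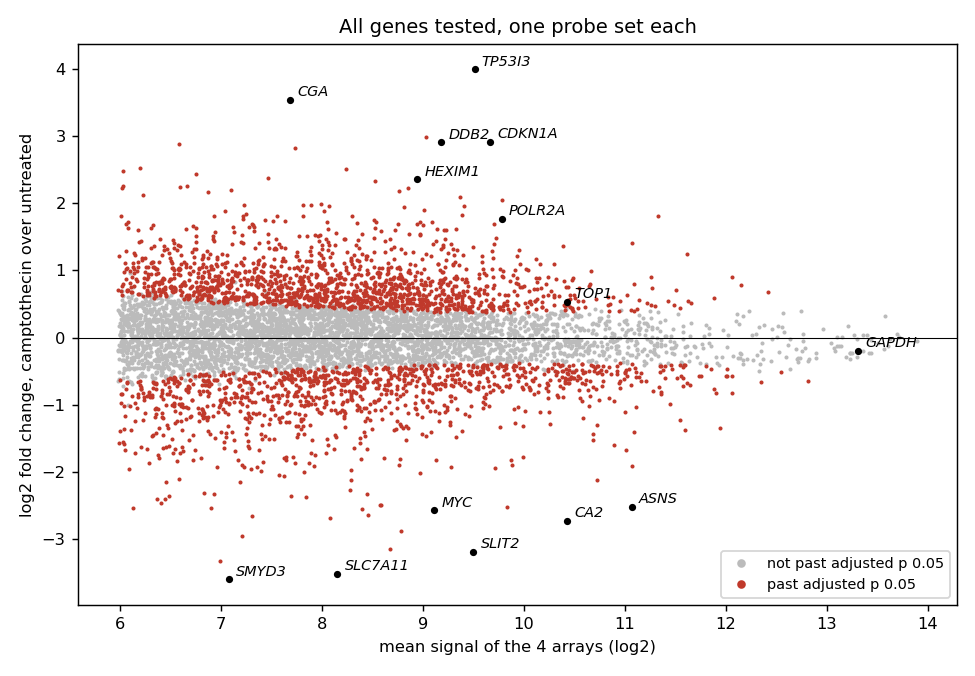
Each point is 1 of the 6803 genes tested, with the mean signal of the 4 arrays (log2) on the horizontal axis and the log2 fold change of camptothecin over untreated on the vertical axis. Red points passed the adjusted p threshold, grey points did not, and labelled black points are genes named in the text, from TP53I3 at 3.99 to SMYD3 at -3.59.

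The 14 largest rises were those of TP53I3, CGA, ACTA2, CDKN1A, DDB2, LIF, SGK1, PLK2, PIDD1, FOSL2, IFITM3, ZMAT3, HEXIM1 and RPRM, with log2 fold changes from 3.99 down to 2.33. CGA, the shared alpha subunit of the glycoprotein hormones, rose by 3.53 (SE 0.20, adjusted p = 1.45e-08), from 19.3 ± 1.77 to 391.95 ± 2.05. ACTA2, smooth muscle alpha-actin, rose by 2.98 (SE 0.16, adjusted p = 8.13e-09) and reached 939 ± 54.0. The cytokine gene LIF rose by 2.87 (SE 0.24, adjusted p = 8.09e-07), and SGK1, a stress-responsive kinase, by 2.82 (SE 0.21, adjusted p = 2.20e-07). HEXIM1, an inhibitor of the elongation factor P-TEFb, rose from 150 ± 7.64 to 834 ± 16.97, a log2 fold change of 2.35 (SE 0.15, adjusted p = 5.71e-08). RPRM, a gene of cell cycle arrest at G2, rose by 2.33 (SE 0.17, adjusted p = 2.47e-07). The value of IFITM3 comes from a probe set that can also bind its close relatives and is uncertain for that reason.

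The 14 largest falls were those of SMYD3, SLC7A11, GPHN, SLIT2, ADK, CHAC1, ASS1, CA2, FAF1, LRBA, TBL1X, MYC, BABAM2 and DIAPH2, with log2 fold changes from -3.59 to -2.54. SMYD3, a histone methyltransferase gene, went from 263 ± 10.4 to 7.30 ± 3.96, a log2 fold change of -3.59 (SE 0.24, adjusted p = 7.38e-08). SLIT2, a secreted guidance cue, went from 1318 ± 22.2 to 131 ± 0.212, a log2 fold change of -3.18 (SE 0.15, adjusted p = 2.17e-09). ADK, adenosine kinase, changed by -3.14 (SE 0.17, adjusted p = 7.80e-09), and ASS1, argininosuccinate synthase, by -2.87 (SE 0.16, adjusted p = 1.08e-08). CA2, carbonic anhydrase 2, went from 2409 ± 53.4 to 351.2 ± 0.495 and GPHN, the scaffold protein gephyrin, from 243 ± 14.4 to 11.2 ± 12.2. The probe set of FAF1 can bind related transcripts. The calls of these 28 genes held in each alternative that tested them.

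**Figure D2:**
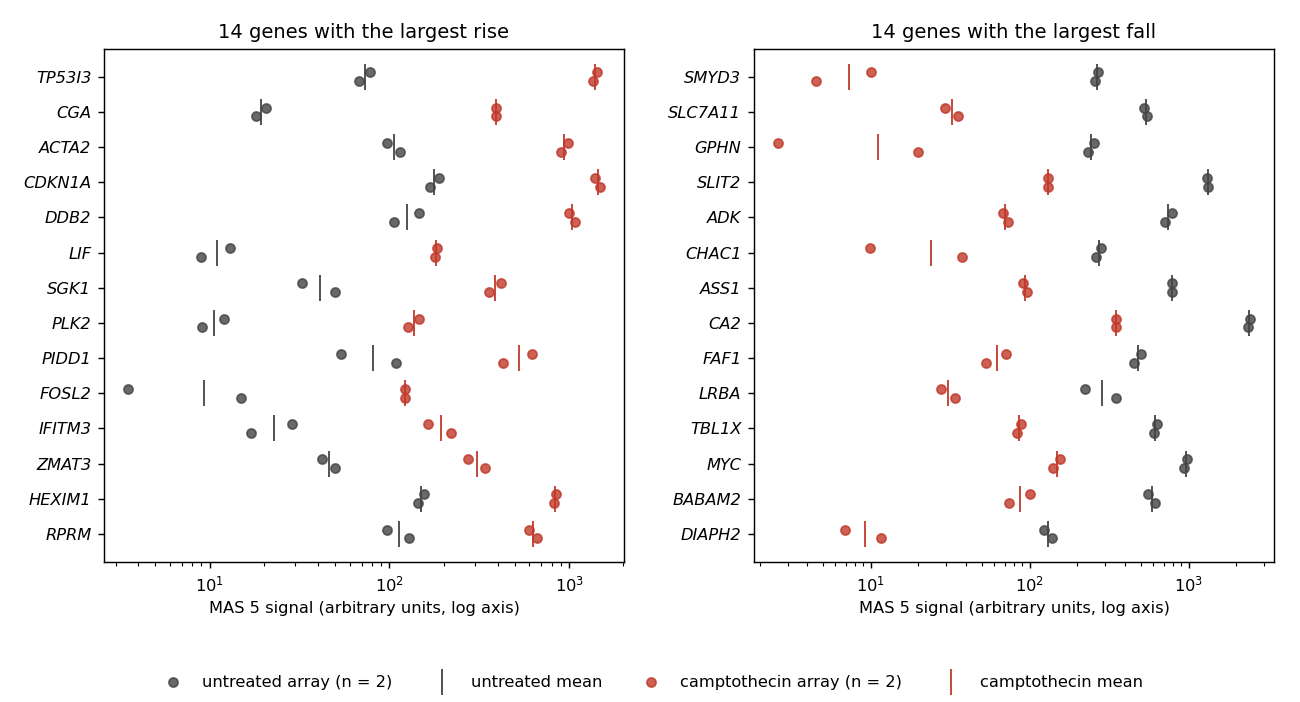
Signal of each array (arbitrary units, log axis) for the 14 genes with the largest rise and the 14 with the largest fall, with untreated arrays in grey, camptothecin arrays in red and a vertical tick at each group mean (n = 2). In all 28 genes both camptothecin arrays lie beyond both untreated arrays, as the rule for naming them requires.

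p53 target genes rose as a group: 22 of the 27 members tested rose, none fell and 5 did not pass the test, and the count was also 22 when adjusted over the list alone. The median log2 fold change was 1.51 (camera adjusted p = 4.82e-15; adjusted p = 0.276 with an estimated correlation). Besides TP53I3, CDKN1A and ACTA2, DDB2, a damage recognition factor of nucleotide excision repair, rose from 126 ± 27.2 to 1036 ± 61.2. MDM2, the ubiquitin ligase that degrades p53, had its representative probe set below the signal limit. Its single tested probe set, which can also bind related transcripts, rose from 36.1 ± 2.83 to 138 ± 16.9, a log2 fold change of 1.56 (adjusted p = 1.06e-04).

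Apoptosis genes also rose as a group, with 9 of 33 members higher, 1 lower and 23 not past the test, the same numbers when adjusted over the list alone. The list's median was 0.31 (camera adjusted p = 0.0168; adjusted p = 0.325 with an estimated correlation), and it shares 4 members with the p53 list. The death receptor genes TNFRSF10B and FAS rose by 1.60 (SE 0.15) and 1.52 (SE 0.20), and the pro-apoptotic BCL2 relatives BAX and BIK by 1.72 (SE 0.16) and 2.22 (SE 0.29). Of these, TNFRSF10B, FAS and BAX are also in the p53 list. The member that fell was CYCS, which encodes cytochrome c, at -0.71 (SE 0.16). Without _x_at and _s_at probe sets the list was not past the test (adjusted p = 0.175), and without untreated replicate 1 its median was 0.21. The median lay inside the central 95% of random lists matched on gene length and signal, -0.08 to 0.34.

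Genes of the integrated stress response and of endoplasmic reticulum stress fell together. Of 37 members tested, 24 fell, 3 rose and 10 did not pass, with 25 falling and 3 rising when adjusted over the list alone. The median was -0.83 (camera adjusted p = 2.67e-10; adjusted p = 0.281 with an estimated correlation). The members with the smallest p were SLC7A11, ASNS, DDIT4 and SLC7A1, all lower: DDIT4, an inhibitor of mTORC1 signalling, went from 1567 ± 96.9 to 261 ± 14.2 (log2 fold change -2.52, SE 0.14), and SLC7A1, a cationic amino acid transporter, from 1585 ± 39.2 to 450 ± 8.91 (-1.78, SE 0.14). CHAC1, a glutathione-degrading enzyme, was also among the 14 largest falls. ATF4, the transcription factor at the centre of this response, changed by -1.34 (SE 0.16), while DDIT3, the stress factor CHOP, had a value of 0.24 (SE 0.20, adjusted p = 0.385). The 3 members that rose were ATF3, a factor that is also in the p53 list, at 1.23 (SE 0.14), PPP1R15A, a phosphatase subunit that acts on eIF2 alpha, at 1.40 (SE 0.18), and the chaperone gene CALR at 0.60 (SE 0.18). The call for CALR was lost without untreated replicate 1 (adjusted p = 0.150) and without camptothecin replicate 1 (adjusted p = 0.184).

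Genes of the G2 phase and mitosis were higher in the camptothecin samples. Of 46 members tested, 25 rose, 2 fell and 19 did not pass, with the same counts when adjusted over the list alone, and the median was 0.51 (camera adjusted p = 6.60e-05; adjusted p = 0.281 with an estimated correlation). CDC25B, a phosphatase that activates cyclin-dependent kinases, rose from 440 ± 34.6 to 1254 ± 12.7 and the kinesin KIF2C from 680 ± 53.7 to 1548 ± 38.7. CCNB2, a mitotic cyclin, and KIF20A, a kinesin of cytokinesis, rose by 1.09 (SE 0.14) and 1.08 (SE 0.15). The 2 members that fell were MAD2L1, a spindle checkpoint gene, at -0.83 (SE 0.24), and CKS1B, a kinase subunit gene, at -0.57 (SE 0.15). The call for MAD2L1 was lost without untreated replicate 1 (adjusted p = 0.246) or camptothecin replicate 1 (adjusted p = 0.204), and that for CKS1B without camptothecin replicate 1 (adjusted p = 0.116).

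DNA replication genes shifted slightly down, with 10 of 44 members lower, 5 higher and 29 not past the test, the same when adjusted over the list alone. The median was -0.20 (camera adjusted p = 0.0314; adjusted p = 0.281 with an estimated correlation). POLA1, the catalytic subunit of DNA polymerase alpha, had a log2 fold change of -2.27 (SE 0.17, adjusted p = 2.03e-07). It spans 303 kb, and most genes of 300 kb and over fell, as given below. GINS1 and CDC45, parts of the replicative helicase, changed by -1.09 (SE 0.16) and -0.87 (SE 0.16). The 5 members that rose were E2F1, a transcription factor of S phase entry, at 1.03 (SE 0.17), and POLE, ORC6, CDT1 and CHAF1B. The list was not past the test with quantile normalization (adjusted p = 0.0657), with spike-in scaling (median -0.089, adjusted p = 0.0791), or without untreated replicate 2 (adjusted p = 0.0502) or camptothecin replicate 1 (median -0.12, adjusted p = 0.0550), and its median was -0.31 without _x_at and _s_at probe sets. Each of POLE, ORC6, CDT1 and CHAF1B lost its call without camptothecin replicate 1, with adjusted p = 0.0868, 0.0864, 0.201 and 0.184. ORC6 also lost it without untreated replicate 2 (0.161) or camptothecin replicate 2 (0.109), CDT1 without untreated replicate 1 (0.146), and CHAF1B without any of the other arrays (0.0599 to 0.121).

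DNA damage checkpoint and repair genes did not move one way: 9 of 40 members fell, 6 rose and 25 did not pass, also when adjusted over the list alone, and the list was not past the test (median -0.07, camera adjusted p = 0.271). The median was 0.03 scaled to the spike-ins, 0.02 in the brightest 30% of probe sets, but -0.13 with a common median, -0.14 in the mean over a gene's probe sets and -0.14 without camptothecin replicate 2. PRKDC, the catalytic subunit of the DNA-dependent protein kinase, fell from 639 ± 155 to 244 ± 16.1, and BARD1, a ubiquitin ligase subunit of homologous recombination, changed by -0.89 (SE 0.18). RAD9A, a subunit of the 9-1-1 checkpoint clamp, rose by 1.04 (SE 0.17), and MUS81, a structure-specific endonuclease, by 0.89 (SE 0.16).

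TOP1, the drug's target, was measured at 1127 ± 173 in untreated and 1630 ± 228 in camptothecin samples, a log2 fold change of 0.53 (SE 0.16, adjusted p = 0.0169). That call was lost without untreated replicate 2 (adjusted p = 0.120) and without camptothecin replicate 2 (adjusted p = 0.190), and its second probe set gave 0.18 (adjusted p = 0.496). In the list of topoisomerases and transcription-coupled repair genes, 5 of 12 members rose, 2 fell and 5 did not pass, also when adjusted over the list alone. The list was not past the test (camera adjusted p = 0.804), and its median of -0.08 and mean of 0.17 differed in sign (median 0.02 with spike-in scaling, 0.03 without _x_at and _s_at probe sets and 0.03 without untreated replicate 1, but -0.22 in the brightest 30% and -0.14 with a common median or without untreated replicate 2). POLR2A, the largest subunit of RNA polymerase II, rose from 391 ± 25.1 to 1366 ± 73.0 (log2 fold change 1.76, SE 0.14, adjusted p = 6.06e-07). TOP3B, a type IA topoisomerase, rose by 0.90 (SE 0.18), and TOP2A and ERCC6 were the other two members that rose. TDP1, which removes trapped topoisomerase I from DNA ends, and TOP2B fell, at -0.73 (SE 0.16) and -0.54 (SE 0.15). Without camptothecin replicate 1 the calls for TOP2A, ERCC6 and TOP2B were lost, with adjusted p = 0.0921, 0.0617 and 0.0791, and with spike-in scaling that for TDP1 (adjusted p = 0.0855). Those for TOP2A and TOP2B were also lost without camptothecin replicate 2 (0.0888 and 0.0575), TOP2A without untreated replicate 2 (0.121) and TOP2B without untreated replicate 1 (0.104).

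Among the immediate early and AP-1 genes, 11 of 21 members rose, 5 fell and 5 did not pass, also when adjusted over the list alone. The median was 0.49 (camera adjusted p = 0.0462; adjusted p = 0.406 with an estimated correlation). FOSL2, a FOS family factor, rose by 2.48 (SE 0.28) from the dim signal of 9.25 ± 8.13, IER3, an early response gene, by 1.504 (SE 0.17), and ATF3 by 1.23 (SE 0.14). The 5 that fell were MYC, at -2.57 (SE 0.15), the AP-1 subunit JUN, at -1.13 (SE 0.18), and KLF10, EGR1 and RHOB. The list was not past the test without untreated replicate 2 (adjusted p = 0.124) or camptothecin replicate 1 (adjusted p = 0.0624). Nor was it with quantile normalization (0.0538), spike-in scaling (0.0525), a pseudocount of 1 (0.0530), the brightest 30% of probe sets (0.330) or fry (0.0564). It was past the camera test without _x_at and _s_at probe sets (median 0.97, adjusted p = 0.0103) and without the signal filter (median 0.46, adjusted p = 0.00705). The main median of 0.49 lay inside its matched random lists, -0.03 to 0.52. Single arrays also ended the calls for KLF10 and EGR1, without untreated replicate 1 (adjusted p = 0.0718 and 0.0832), for RHOB, without untreated replicate 2 (adjusted p = 0.129), and for EGR1 and RHOB, without camptothecin replicate 2 (adjusted p = 0.0516 and 0.157).

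NF-kB target genes and interferon response genes were higher in camptothecin. Of the NF-kB list 5 of 10 members rose and none fell, also when adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.0163; adjusted p = 0.281 with an estimated correlation). Its rising members were IER3, NFKBIA, NFKB2, ICAM1 and TNFAIP3, and NFKBIA, the inhibitor that NF-kB itself induces, went from 257 ± 12.7 to 502 ± 46.6. The TNFAIP3 call was lost without camptothecin replicate 2 (adjusted p = 0.110). Of the interferon list 9 of 16 members rose and none fell, also when adjusted over the list alone, with a median of 0.63 (camera adjusted p = 2.61e-04; adjusted p = 0.281 with an estimated correlation). HLA-B, a class I antigen-presenting molecule, rose from 1869 ± 170 to 4424 ± 253, IFI35 by 1.66 (SE 0.21) and IRF9, a subunit of the interferon-activated factor ISGF3, by 1.57 (SE 0.21). Probe sets of HLA-B and IFITM3 can bind relatives. Without _x_at and _s_at probe sets neither list passed (median 0.14, adjusted p = 0.524 for NF-kB; median 0.48, adjusted p = 0.0931 for interferon), but this drops all 5 rising NF-kB members and IFI35, whose probe sets are named _s_at. In the brightest 30% of probe sets the NF-kB median was 0.92. Without the signal filter the NF-kB list was not past the test (median 0.22, adjusted p = 0.0847) and the interferon median was 0.37 (adjusted p = 0.00412). The NF-kB median lay inside its matched random lists, -0.17 to 0.62, and the interferon median above its own, -0.04 to 0.60.

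Lysosome and autophagy genes rose, with 16 of 29 members higher, 2 lower and 11 not past the test, also when adjusted over the list alone. The median was 0.54 (camera adjusted p = 2.95e-04; adjusted p = 0.325 with an estimated correlation). NEU1, a lysosomal sialidase, went from 176 ± 28.8 to 720 ± 86.8, MCOLN1, a lysosomal calcium channel, rose by 1.27 (SE 0.17) and ULK1, the kinase that starts autophagy, by 1.22 (SE 0.17). ATP6V1B2, a subunit of the lysosomal proton pump, rose by 0.98 (SE 0.14). The 2 members that fell were the autophagy conjugation gene ATG5, at -0.78 (SE 0.17), and the galactosidase gene GLA, at -0.51 (SE 0.14). The call for GLA was lost without untreated replicate 2 and without either camptothecin array, with adjusted p from 0.0556 to 0.124.

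Cholesterol and fatty acid synthesis genes fell, with 10 of 24 members lower, 2 higher and 12 not past the test, and 11 lower and 2 higher when adjusted over the list alone. The median was -0.34 (camera adjusted p = 5.85e-04; adjusted p = 0.281 with an estimated correlation), and -0.72 without _x_at and _s_at probe sets. SCD, stearoyl-CoA desaturase, went from 1495 ± 253 to 389 ± 18.7, ACACA, acetyl-CoA carboxylase, from 318 ± 85.8 to 63.95 ± 15.5 and INSIG1, a sterol sensor, from 955 ± 0.141 to 332 ± 15.9. The 2 members that rose were TM7SF2, a sterol reductase gene, at 1.71 (SE 0.16), and HSD17B7, at 0.56 (SE 0.15), whose call was lost without camptothecin replicate 2 (adjusted p = 0.0732).

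Genes of ribosomal RNA synthesis and ribosome assembly fell, with 12 of 34 members lower, 3 higher and 19 not past the test, also when adjusted over the list alone. The median was -0.26 (camera adjusted p = 0.01004; adjusted p = 0.281 with an estimated correlation), and -0.17 with spike-in scaling. Besides MYC, the helicase gene DDX10 went from 693 ± 47.8 to 175 ± 16.3 and PNO1, an assembly factor of the small subunit, from 563 ± 34.9 to 292 ± 1.56. TAF1C, a subunit of the RNA polymerase I factor SL1, rose by 1.21 (SE 0.17), and FTSJ3 and UBTF were the other two that rose. Their calls were lost without untreated replicate 1 (adjusted p = 0.150 and 0.208), camptothecin replicate 1 (0.0913 and 0.130) or camptothecin replicate 2 (0.127 and 0.224).

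Few cytoplasmic ribosomal protein genes passed the test singly. Of 50 members 1 rose, 2 fell and 47 did not pass, and none did when adjusted over the list alone, although 5081 of the 11111 probe sets had an unadjusted limma p under 0.05. The list lay below the other genes, with a median of -0.16 (camera adjusted p = 0.0240; adjusted p = 0.760 with an estimated correlation). The member that rose was RPL31, and 0 of its 2 other tested probe sets rose with it. The changes of RPL31, RPL11 and RPL38 were 0.62 (SE 0.16), -0.58 (SE 0.16) and -0.46 (SE 0.16). These calls were lost without camptothecin replicate 2 (adjusted p = 0.0795, 0.0647 and 0.255), those for RPL31 and RPL38 without untreated replicate 2 (0.0797 and 0.0663), that for RPL11 without camptothecin replicate 1 (0.186) and that for RPL38 without untreated replicate 1 (0.144). The list's median was -0.30 without untreated replicate 1 (adjusted p = 8.34e-07), and the list was not past the test without untreated replicate 2 (median -0.021, adjusted p = 0.467) or camptothecin replicate 2 (adjusted p = 0.0836). Nor was it with quantile normalization (median -0.060, adjusted p = 0.270), spike-in scaling (median -0.048, adjusted p = 0.0799), fry (0.381) or without _x_at and _s_at probe sets (0.0931).

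Spliceosome and RNA processing genes shifted down, with 15 of 44 members lower, 4 higher and 25 not past the test, also when adjusted over the list alone. The median was -0.20 (camera adjusted p = 0.0325; adjusted p = 0.281 with an estimated correlation). SNRPE, a core protein of the spliceosomal snRNPs, fell from 3357 ± 8.77 to 1906 ± 163. The 4 members that rose were RBM5, a splicing regulator, from 388 ± 22.8 to 1285 ± 23.8, the kinases of SR proteins CLK1 and CLK4, at 1.23 (SE 0.23) and 0.94 (SE 0.18), and PRPF3, at 0.55 (SE 0.16). Without camptothecin replicate 1 the list (adjusted p = 0.0683) and PRPF3 (adjusted p = 0.0737) were not past the test, nor was PRPF3 without untreated replicate 1 (0.110) or camptothecin replicate 2 (0.0890). The list was also not past the test with quantile normalization (median -0.12, adjusted p = 0.197), spike-in scaling (median -0.090, adjusted p = 0.111), without _x_at and _s_at probe sets (0.112) or with the mean over a gene's probe sets (0.0947).

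Oxidative phosphorylation genes were slightly lower, with 9 of 42 members falling, 2 rising and 31 not past the test, and 7 falling and 2 rising when adjusted over the list alone. The median was -0.21 (camera adjusted p = 0.0162; adjusted p = 0.406 with an estimated correlation), and the list was not past the test with quantile normalization (median -0.10, adjusted p = 0.270) or spike-in scaling (median -0.11, adjusted p = 0.0525). NDUFS4, a subunit of complex I, went from 657 ± 23.5 to 255 ± 1.34 and COX5A, a subunit of complex IV, from 2892 ± 65.9 to 1839 ± 14.1. SDHA, of complex II, rose by 0.77 (SE 0.14) and NDUFA2 by 0.57 (SE 0.15), the latter call being lost without untreated replicate 1 (adjusted p = 0.0606) and camptothecin replicate 1 (adjusted p = 0.0868). The probe set of SDHA can bind several transcripts. Glycolysis and hypoxia genes went both ways, with 8 of 27 members lower and 5 higher, 9 and 6 when adjusted over the list alone, and were not past the test as a list (median -0.20, camera adjusted p = 0.185). VEGFA, the angiogenic growth factor, and ENO1, a glycolytic enolase, fell by 1.36 (SE 0.18) and 0.84 (SE 0.15). ALDOC and ENO2, the brain forms of aldolase and enolase, rose by 1.81 (SE 0.18) and 1.64 (SE 0.19), and ADM, P4HA2 and BNIP3L also rose. BNIP3L turned to -0.085 without _x_at and _s_at probe sets (adjusted p = 0.725) and was not past the test in the mean over its probe sets (adjusted p = 0.0569), and the call for ADM was lost without camptothecin replicate 2 (adjusted p = 0.0567). Without untreated replicate 1 the list was past the test (median -0.30, adjusted p = 0.0419), while the median was -0.066 without untreated replicate 2, -0.088 with quantile or spike-in scaling and -0.093 without _x_at and _s_at probe sets.

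Cytoskeleton and serum response factor target genes were higher, with 12 of 28 members rising, 1 falling and 15 not past the test, and 12 rising and 2 falling when adjusted over the list alone. The median was 0.22 (camera adjusted p = 0.0314; adjusted p = 0.281 with an estimated correlation). LMNA, which encodes the nuclear lamins A and C, rose from 271 ± 70.6 to 1087 ± 185, TPM2, a tropomyosin, by 1.69 (SE 0.25) and CCN1, a matrix-associated signalling protein, by 1.23 (SE 0.20). TUBB, a beta-tubulin gene, was the member that fell, at -0.67 (SE 0.14), a call lost in the mean over its probe sets (adjusted p = 0.221). The list was not past the test in the brightest 30% of probe sets (adjusted p = 0.0789) or without _x_at and _s_at probe sets (adjusted p = 0.134), and without the signal filter its median was 0.11 (adjusted p = 0.0207). The common reference genes GAPDH and ACTB were not past the test, with log2 fold changes of -0.20 (SE 0.19, adjusted p = 0.444) and -0.22 (SE 0.19, adjusted p = 0.382). The value of GAPDH was 0.031 without untreated replicate 2, and without untreated replicate 1 it was past the test at -0.43 (adjusted p = 0.0234).

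**Figure D3:**
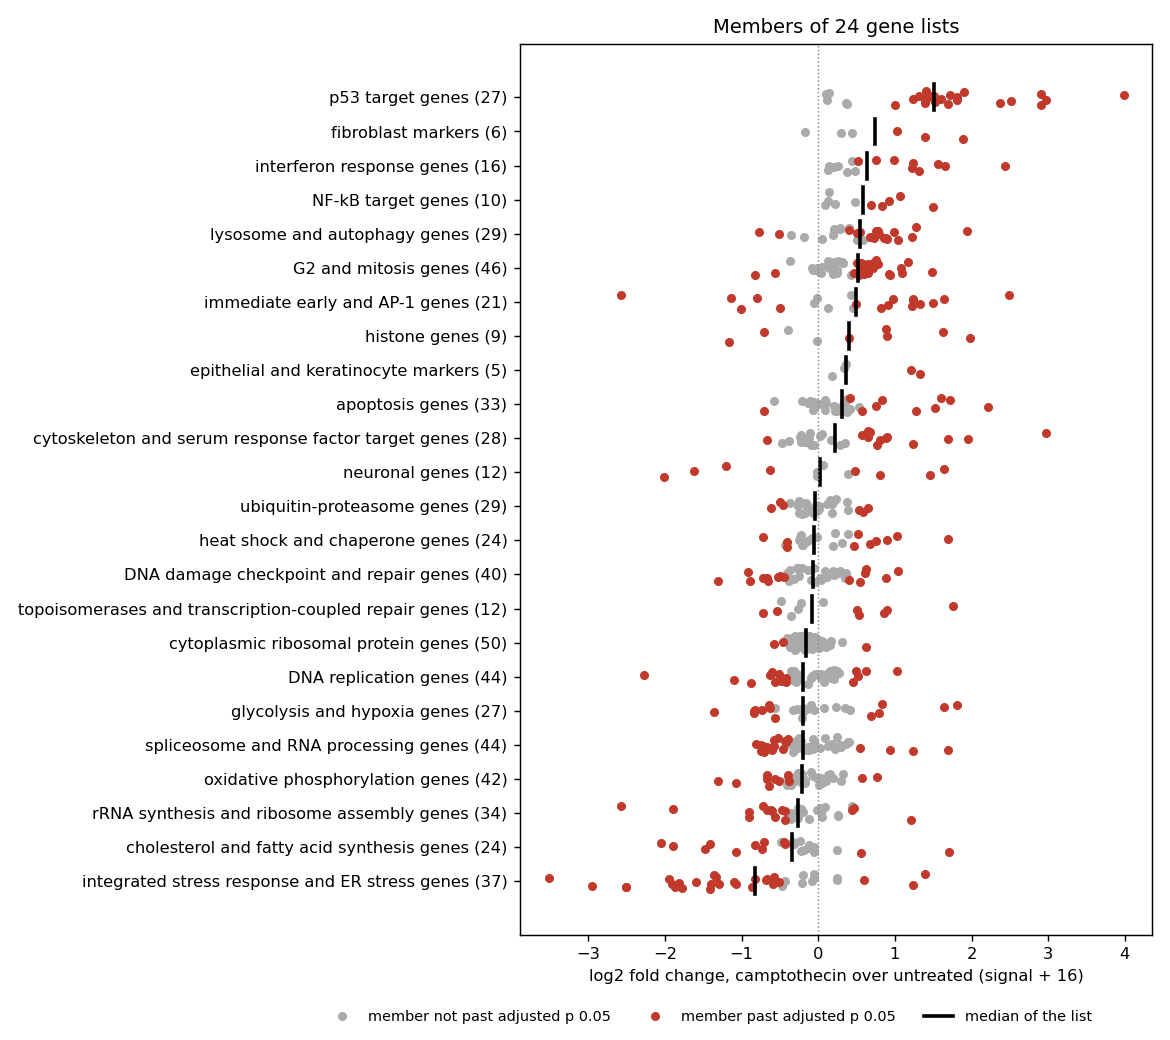
Each point is the log2 fold change of 1 member of a gene list, camptothecin over untreated on the log2(signal + 16) scale, with the number of members tested in parentheses. Red points passed the adjusted p threshold, grey points did not, and black bars are the list medians, from 1.51 for the p53 target genes to -0.83 for the integrated stress response and endoplasmic reticulum stress genes.

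Histone, chaperone and proteasome genes were not past the test as lists. Of 9 histone genes 5 rose and 2 fell, 5 and 3 when adjusted over the list alone (median 0.40, camera adjusted p = 0.313). The histone list was past the test without the signal filter (median 0.18, adjusted p = 0.0305) and by fry (adjusted p = 0.0212). H2BC5, H1-2, H2BC12, H2BC6 and H2AX rose, H2BC5 and H1-2 by 1.98 (SE 0.18) and 1.62 (SE 0.21), and H4C11 and H2AZ1 fell, at -1.16 (SE 0.21) and -0.71 (SE 0.15). Many histone genes are near-identical copies, which makes some of these assignments uncertain. This holds above all for H2BC5 and H4C11, whose probe sets can bind several transcripts. The H2AX and H2AZ1 calls were lost without camptothecin replicate 1, that for H2AX also without any other array. Of 24 heat shock and chaperone genes 7 rose and 3 fell, 7 and 4 when adjusted over the list alone, with a median of -0.05 (0.08 with quantile normalization and 0.06 with spike-in scaling, but -0.12 with a common median or in the brightest 30%) and a mean of 0.15 that differ in sign (camera adjusted p = 0.766). The co-chaperones DNAJB4, DNAJB1 and BAG3 rose by 1.69 (SE 0.21), 0.75 (SE 0.14) and 0.89 (SE 0.17), and HSPE1, CCT2 and CCT5, which encode parts of chaperonins, fell. The calls for CCT2 and CCT5 were lost without untreated replicate 2 (adjusted p = 0.0632 and 0.112), camptothecin replicate 1 (0.345 and 0.189) or camptothecin replicate 2 (0.115 and 0.272), and that for CCT2 without untreated replicate 1 (0.0638). Of 29 ubiquitin-proteasome genes 3 rose and 3 fell, also when adjusted over the list alone (median -0.05, 0.03 with quantile normalization, 0.06 with spike-in scaling and 0.16 without _x_at and _s_at probe sets, but -0.11 with a common median and -0.093 without untreated replicate 1; camera adjusted p = 0.636). PSMD3, a proteasome lid subunit, rose by 0.64 (SE 0.14), as did PSMD2 and UBA1, while PSMD14, PSMA2 and PSMC6 fell. PSMA2 turned to 0.16 without _x_at and _s_at probe sets (adjusted p = 0.462). Apart from PSMD3, these calls were lost without camptothecin replicate 1, with adjusted p from 0.0616 to 0.257. Those for PSMD2, PSMA2 and PSMC6 were also lost without untreated replicate 1 (0.0677, 0.0649 and 0.103), and that for PSMC6 without untreated replicate 2 (0.0866).

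Markers of other cell types were measured on the same arrays. Of 6 fibroblast markers tested COL1A1, SPARC and MMP2 rose, by 1.89 (SE 0.20), 1.39 (SE 0.19) and 1.03 (SE 0.24), and none fell, also when adjusted over the list alone. Their median was 0.74 (camera adjusted p = 0.0378; adjusted p = 0.541 with an estimated correlation), and COL1A1 reached 217 ± 6.36. Of 5 epithelial markers KRT18 and KRT8, keratins of simple epithelia, rose by 1.21 (SE 0.14) and 1.33 (SE 0.18), also when adjusted over the list alone (median 0.37, camera adjusted p = 0.0314; adjusted p = 0.291 with an estimated correlation). Without untreated replicate 2 neither list was past the test, with medians of 0.49 and 0.21 (adjusted p = 0.164 and 0.101), and without camptothecin replicate 1 the fibroblast list was not (adjusted p = 0.0691). Neither passed without the signal filter (medians 0.16 and 0.21, adjusted p = 0.248 and 0.227), the fibroblast list did not by fry (0.0905), and the epithelial median lay inside its matched random lists, -0.42 to 0.55. The probe sets of KRT18 and KRT8 can each bind several transcripts. The 2 blood cell markers tested, CORO1A and LCP1, rose by 0.87 (SE 0.25) and 0.60 (SE 0.19), also when adjusted over the list alone, and both calls were lost without untreated replicate 1 (adjusted p = 0.0950 and 0.0849) or camptothecin replicate 1 (adjusted p = 0.117 and 0.210). Of 12 neuronal genes, a class that 293T cells express in part, NEFM, SYT1, NCAM1 and VSNL1 fell and INA, ENO2, TUBB3 and UCHL1 rose, also when adjusted over the list alone (median 0.02, mean -0.06, camera adjusted p = 0.962). The median was negative with quantile and common median scaling, at -0.010 and -0.033, and without _x_at and _s_at probe sets, at -0.32, while it was 0.48 in the brightest 30%. NEFM, the medium neurofilament chain, went from 814 ± 52.4 to 189 ± 7.85 and INA, internexin alpha, from 168 ± 1.63 to 489 ± 6.08. The VSNL1 and UCHL1 calls were lost without untreated replicate 1 (adjusted p = 0.165 and 0.120), camptothecin replicate 1 (0.118 and 0.117) or camptothecin replicate 2 (0.122 and 0.121), that for VSNL1 also without untreated replicate 2 (0.106), and that for NCAM1 without untreated replicate 2 (adjusted p = 0.0541).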

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

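The crossed block was chosen after the data were seen, the other alternatives before. Past the threshold were 17 gene lists. Those of p53 targets, integrated stress response, G2 and mitosis, lysosome, cholesterol synthesis and ribosome assembly kept their call in every alternative except the estimated correlation. There 0 lists passed, with the correlation estimated from 2 residual degrees of freedom. The estimates were -0.031 for p53 targets, -0.020 for G2 and mitosis, -0.025 for cholesterol synthesis and -0.0086 for ribosome assembly. These are below the preset 0.01, so a higher correlation is not what ended those calls. For the integrated stress response and lysosome lists the estimates were 0.145 and 0.138. An estimated correlation also makes camera refer its statistic to the 2 residual degrees of freedom, which the preset correlation does not. Only a very large statistic can then pass, so the loss of these calls does not show that the lists did not move. Of 164 named genes 157 passed; 47 of these lost the call in at least 1 alternative, 41 of them without one of the arrays, and 2 reversed. Of the 2583 called genes, 2364 were called with quantile normalization, 2378 with a common median and 1567 with spike-in scaling, and 0 in the opposite direction.

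With fewer probe sets to test, the brightest 30% gave 1444 probe sets higher, and leaving out _x_at and _s_at names gave 1000 higher and 786 lower, 836 and 648 genes and 9 lists. Spike-in scaling, which shifts fold changes up, left 812 probe sets and 536 genes lower. Fewer were higher as well, 1582 probe sets and 1049 genes, so the shift alone does not account for these counts. This scaling also moved the untreated arrays apart. Their mean log2 spike-in signals were 8.94 and 9.32, while their trimmed mean signals were both 200.07. That adds to the spread within the untreated group, which lowers counts in both directions. How much of the drop it accounts for was not tested. Without 1 array, 1268 to 1874 probe sets were higher and 1131 to 1554 lower, 868 to 1241 genes higher and 717 to 966 lower, and 12 to 18 lists passed. Genes 2-fold in all pairs numbered 231 with a pseudocount of 64, which shrinks folds, 234 in the brightest 30%, 236 without _x_at and _s_at names and 525 to 610 without 1 array, which leaves fewer pairs to pass. With a block for the sample number, 2044 probe sets and 1348 genes were higher, 1674 and 1035 lower, and 13 lists passed. The crossed block gave 2782 and 1836 higher, 2318 and 1422 lower, and 15 lists.

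Reversals were in lists not past the threshold and in single genes; the cause was not tested. For lists, it is the direction of the camera test that turned, and the medians beside it need not change sign. The camera direction of the heat shock list, up with a median of -0.051, was down in the brightest 30% (median -0.12), without _x_at and _s_at names (-0.054) and without untreated replicate 1 (-0.068). Its median alone was positive with quantile normalization (0.079) and spike-in scaling (0.058), and -0.087 to 0.036 without 1 array. The direction of the ubiquitin-proteasome list, down with a median of -0.045, was up with quantile normalization (0.027) and without those names (0.16). That of the neuronal list, down with a median of 0.022, was up with quantile normalization (-0.010), a common median (-0.033), no filter (0.17), the brightest 30% (0.48), and without untreated replicate 2 (0.10) or camptothecin replicate 1 (0.11), with medians of 0.039 to 0.11 without 1 array. BNIP3L (-0.085) and PSMA2 (0.16) turned without those names, and GAPDH without untreated replicate 2 (0.031; without 1 array -0.43 to 0.031). Genes near the background signal have folds that depend on the pseudocount.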

Other observations

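The gene families, the question of gene length and, on it, the tests with 20 signal bins, of same-group spread in the longest genes and of the longest genes without the most fallen ones were chosen after results were seen, as was the test of fibroblasts as a part of the p53 rise. Transcripts of the large subunit of the mitochondrial ribosome were lower in camptothecin. Of its 28 tested genes (symbols beginning MRPL), 14 fell and 1 rose, with a median log2 fold change of -0.36 (camera adjusted p = 0.00199 over 98 symbol families; adjusted p = 0.999 with an estimated correlation). MRPL48 went from 647 ± 39.5 to 246 ± 24.1 and MRPL3 from 2138 ± 134 to 930 ± 172, while MRPL49 rose by 0.51, a call lost without untreated replicate 1 (adjusted p = 0.156), untreated replicate 2 (0.0536) or camptothecin replicate 1 (0.370). Of 19 genes of the small subunit (MRPS), 7 fell and 0 rose, and that family was not past the threshold (median -0.34, camera adjusted p = 0.0875). Of 9 HLA genes, which encode antigen-presenting molecules, 8 rose and 0 fell, with a median of 0.74 (camera adjusted p = 0.0256; adjusted p = 0.999 with an estimated correlation). HLA-DMB, a class II gene, went from 137 ± 1.98 to 323 ± 17.9. HLA genes resemble one another, so several probe sets can report the same transcript. Both medians kept their sign under each scaling, from -0.43 to -0.26 for MRPL and from 0.67 to 0.85 for HLA.

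Genes with a long genomic span fell more. Of 163 tested genes of 300 kb and over, 113 fell and 6 rose, with a median log2 fold change of -1.13, against 147 that fell and 420 that rose among 1356 genes under 10 kb, with a median of 0.19. SMYD3 spans 758 kb and GPHN 1227 kb, and the median length was 409 kb for the 14 largest falls and 9.96 kb for the 14 largest rises. Spearman's rho of fold change with length across 6802 genes, which are not independent replicates, was -0.318, and -0.256 to -0.346 under the alternatives. MYC and CHAC1, at 7.52 and 3.04 kb, fell without being long. Among the members named with their lists, POLA1 (303 kb), ACACA (322 kb), DDX10 (276 kb) and SYT1 (588 kb) fell and are long. Their falls cannot be told apart from the length trend. GINS1 (40.9 kb), SCD (17.6 kb), PNO1 (18.4 kb) and NEFM (5.33 kb) fell and are shorter.

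The tables argue against low signal as the whole source of the trend: the mean rho over 20 signal bins was -0.351 (bootstrap SE 0.0114), and the 1st percentile of lists matched on the signal of the longest class was -0.0095. In the 5 signal quintiles rho was -0.514, -0.408, -0.419, -0.264 and, among the brightest genes, -0.107 (bootstrap SE 0.0276). The limit of -0.1 was therefore not passed there by more than its spread. Lists of shorter genes matched on the signal of the longest class had a median of 0.114, so equally dim genes did not fall as a set. That argues against low signal as a part of the source in the longest class. Over all genes low signal as a part stays open by that limit, although the mean rho over the signal bins was no weaker than the -0.318 without bins. Without the most fallen genes, which prompted the question, the median of the other 139 genes of the longest class was -0.98 (bootstrap SE 0.099). Since 113 of the 163 genes of that class fell, leaving some out could not turn its median upward, so its sign decides nothing. The value shows that the fall in this class was not confined to the most fallen genes. Leaving those genes out of all 6802 gave a rho of -0.311, which decides nothing because 39 genes can hardly move it. RNA degradation is argued against by the 3' to 5' signal ratios of the controls, treated over untreated, which were 1.07 for GAPDH and 0.928 for ACTB between group means, and 1.22 and 1.02 for the highest treated over the lowest untreated array.

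Same-group spread is argued against in the longest class, where the larger median difference between arrays of a group was 0.097. For the trend over all genes, rho was 0.191 between the untreated arrays and -0.028 between the camptothecin arrays, and -0.341 to -0.259 in the 4 treated-untreated pairs. The 4 pairs share a sign, but 0.191 is too large a share of the treatment's -0.318 for the limit set beforehand, and a length trend between arrays of a group stays open as a contribution. Trapped topoisomerase I may hold up transcription of long genes, and the longest class had the lowest median, -1.13. The medians were 0.187 under 10 kb, 0.195 at 10 to 30 kb, 0.053 at 30 to 100 kb and -0.330 at 100 to 300 kb. They fell at each step except between the 2 shortest classes, which differed little. The prediction of a fall at each step was thus not met, and the hypothesis stays undecided.

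p53 target genes rose with a median of 1.51, although 293T cells carry the large T antigen, which binds p53. The tables argue against dim probe sets, since the 20 members with an untreated signal of at least 100 had a median of 1.47, and against short genes of middling signal rising in general, since the 99th percentile of matched random lists was 0.40. Cells of another type as the source of the whole rise were weighed by the 3 marker lists, with the blood cell list resting on 2 genes. Their highest median, 0.74 for the fibroblast markers, lay below that of the p53 list by 0.78 (bootstrap SE 0.42). That is past the limit of 0.3 by little more than 1 SE, and the demand for 1 SE was set after the values were seen. The lists therefore do not exclude this explanation. Fibroblasts as a part of the rise stay open as well. Their markers were higher as a list, with members from -0.17 to 1.89, but with a median of 0.16 and not past the test without the signal filter. A response to the drug may be the source. The list was fixed before the data were examined, but no test here separates such a response from differences in vehicle or culture. The labels do not give these, and they stay open too.

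Genes of the integrated stress response fell, with ATF4 at -1.34 and ASNS at -2.51. Gene length is argued against, since the 1st percentile of matched random lists was -0.15 and the list's median -0.83. A single array is argued against, since the median stayed between -0.90 and -0.76 without any one of them. Differences in medium or cell density between the cultures stay open, since no value here tests them.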
